A study of Homo sapiens with 9 samples.

How the data were processed

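The cells were 293T, an established human embryonic kidney line that carries the SV40 large T antigen. Per the labels, they were treated with a scramble shRNA or with an shRNA against DIS3, the catalytic 3' to 5' exonuclease and endonuclease of the nuclear RNA exosome. The labels name 9 samples in 3 groups of 3: Scramble, DIS3-sh1 and DIS3-sh2. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted with a RiboMinus kit, and libraries were made with the Illumina TruSeq Stranded Total RNA kit and sequenced on an X-ten instrument. Such libraries hold coding and non-coding transcripts with and without poly(A) tails, and RNAs much shorter than the selected fragments are captured poorly.

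The deposited table holds expected counts per gene, that is, read counts that need not be whole. Per the submitters' processing notes, Bowtie2 2.3.5, HISAT2 2.1.0, SAMtools and featureCounts 1.5.1 were used with genome build hg38. The role and settings of each tool, the annotation version and the use of strand in counting were not given in the sources used here. Between 53.24% and 56.03% of the values above 0 in a library were whole numbers, and the rest were fractions. Reads that matched several genes or places therefore seem to have been split, so values of near-identical paralogs, pseudogenes and overlapping genes are uncertain. Since the use of strand is not stated, the same holds for antisense genes and for genes inside others.

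The table has 9 columns of per-sample values. Column names matched the labels of the 3 Scramble and the 3 DIS3-sh1 libraries. The names of the other 3 columns matched no sample label, so these 3 columns were not used in any step, and DIS3-sh2 is not analysed here. They may hold the DIS3-sh2 libraries under another name, which the labels do not settle. Results that had been planned for DIS3-sh2, for both shRNAs together and for the difference between the shRNAs were therefore not computed, and the model was fitted to 6 libraries instead of the 9 it was written for. Circular RNAs have no values of their own in the columns used and were not analysed here.

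The 6 libraries held between 19800892 counts (DIS3-sh1 replicate 2) and 23532148 counts (Scramble replicate 1). Of 61853 genes listed, 36854 had a count in at least 1 of them. Gene symbols were found for 61757 of the identifiers. Gene types and coordinates came from GENCODE 29 on GRCh38, which holds 58298 of the identifiers. Values were rounded to whole counts before the tests, which moved no library total by more than 0.0014%.

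Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, edgeR's expression filter by group, a negative binomial model with group as the only term, and the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all 19591 genes that passed the filter. Genes with an adjusted p under 0.05 are called higher or lower in DIS3-sh1. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. Values per library are TMM-scaled CPM, given as mean ± SD with n = 3 per group. Every adjusted p given for a single gene is from this test unless another setting is named beside it.

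Before the data were examined, 34 gene lists, the tests, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members (31 lists) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated per list, and fry gave a test of each list on its own. With an estimated correlation, camera also rests on the few residual degrees of freedom of 6 libraries. A call lost in that setting therefore need not come from correlated members. The rule named DIS3, the 5 genes with the largest increase and the 5 with the largest decrease among called genes with a mean of at least 1 CPM, a proper symbol and no overlap between the groups, up to 4 members of each list with the smallest p, and every member of the exosome list. The parts of the rule that need DIS3-sh2 could not be used, and the list members were ranked by the DIS3-sh1 comparison in place of the average over both shRNAs. The rule gave 167 genes. Another 43 genes were chosen after their values were seen: EIF4G2, CCND2, TSC22D3, RN7SL1, SNORD3A, SNORD3B-1, SCARNA2, DIS3L2, and members that went against the rest of their list.

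The fit was tested on simulated data drawn from the libraries' own means, sizes and dispersions, with 200 of 19591 genes changed. It called 44% of genes changed by a fold of 1.25, 66% at a fold of 1.5, 86% at a fold of 2 and 94% at a fold of 4. False calls made up 7.05% of all calls, and 2 genes were called when none had been changed. These shares belong to a setting with few changed genes, unlike the data, and need not carry over. Of 1 changed list and 30 random lists, camera called the changed list and 0 random lists, with the preset and with the estimated correlation. Genes were drawn independently of each other in this simulation, and only the changed list was given an effect. It therefore does not show how camera treats lists of correlated genes, or data in which most genes change.

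The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving small structural RNA, ribosomal RNA and mitochondrial genes out before scaling, a test against a fold of 1.2 (glmTreat), and leaving out each library in turn. Tests of possible technical causes used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, with 10000 bootstrap draws for medians and 2000 for Spearman's rho and for the differences of medians between carriers of a sequence word. The draws resampled genes and not libraries. Their intervals therefore measure the spread across genes, which are not independent replicates, and not the spread between libraries. For the search of 3' untranslated regions (UTRs), the longest annotated 3' UTR per coding gene was used, and words of 7 bases were tested where at least 100 genes carried them, with the fold changes adjusted for the length and GC content of the UTR. In a test on shuffled fold changes of 13694 genes, a word that had been given a negative effect came out with rank 1, and the strongest negative z with no effect given was -4.13.

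No 2 libraries held the same values. The chi-square of the counts over its degrees of freedom, over genes with a sum of at least 10, was 1.89 to 1.97 for pairs of Scramble libraries and 1.61 for DIS3-sh1 replicates 2 and 3, where sampling noise alone gives about 1. It was 5.72 and 5.82 for DIS3-sh1 replicate 1 against replicates 2 and 3, so that replicate 1 stands apart within its group. Pairs of libraries from different groups gave 67.1 to 84.2. The series design calls the replicates biological. Nothing in the labels says whether they came from separate transductions, so the p-values measure the spread between these libraries.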

Results

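The transcriptome of 293T cells was measured by RNA sequencing after ribosomal RNA depletion, with 3 libraries from cells given a scramble shRNA (Scramble) and 3 from cells given an shRNA against DIS3 (DIS3-sh1). The series asks how loss of DIS3 changes the expression of circular RNAs. The values analysed here are per gene, and they address what DIS3-sh1 did to linear, coding and non-coding transcripts. Library totals ranged from 20722775 to 23532148 counts in Scramble and from 19800892 to 21100677 counts in DIS3-sh1, so a gene at 1 CPM rests on about 20 counts in a library.

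DIS3, the target of the shRNA, was lower in all 3 DIS3-sh1 libraries than in any Scramble library. The gene (ENSG00000083520.15) lies on the minus strand of chromosome 13 at 72752169 to 72782096 in hg38. It measured 175.8, 186.1 and 177.1 CPM in the Scramble libraries and 26.6, 27.8 and 27.9 CPM in the DIS3-sh1 libraries. The means were 180 ± 5.62 CPM and 27.4 ± 0.73 CPM (SD, n = 3 each), a log2 fold change of -2.71 ± 0.04 (SE, edgeR quasi-likelihood test, adjusted p = 6.76e-30). DIS3L, the cytoplasmic paralog of DIS3, rose by a log2 fold change of 0.45 ± 0.06. DIS3L2, an exosome-independent paralog, measured 32.9 ± 0.76 CPM in Scramble and 31.8 ± 0.64 CPM in DIS3-sh1 and did not pass the test (adjusted p = 0.458).

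**Figure D1:**
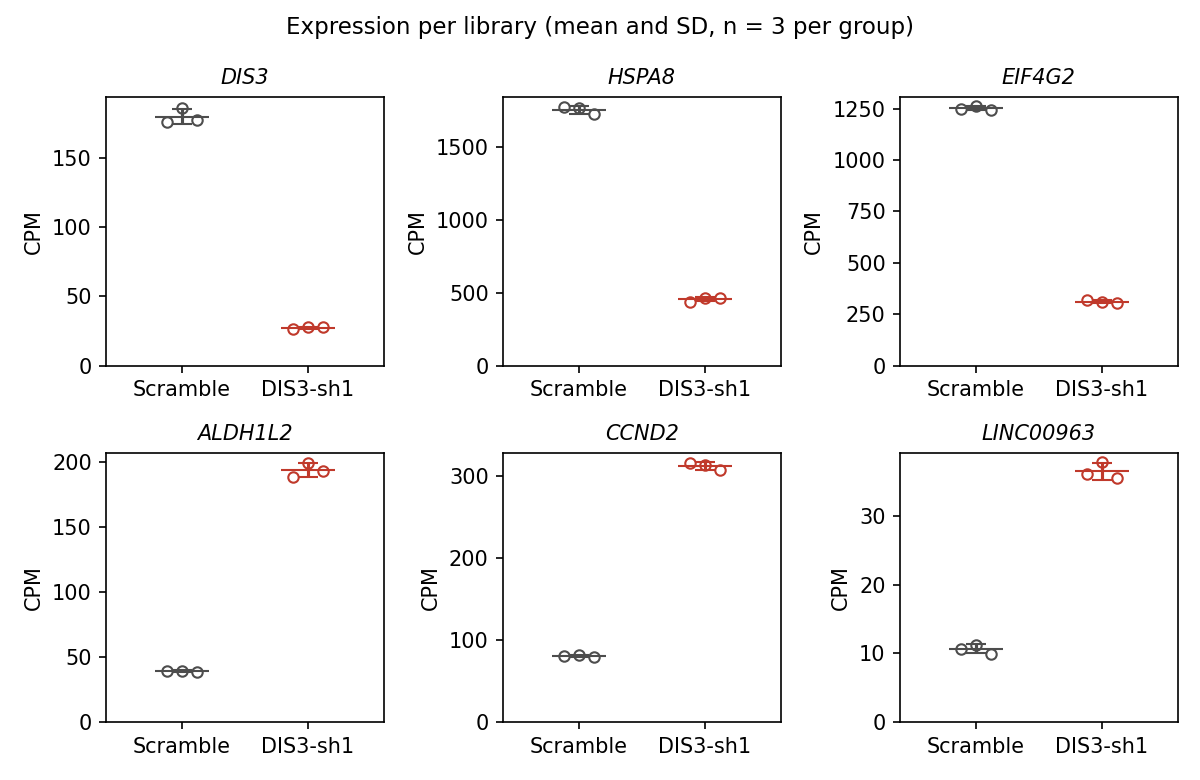
Expression of 6 genes in CPM in each Scramble and each DIS3-sh1 library. Circles are libraries, and bars are the mean and SD of 3 libraries per group. DIS3, HSPA8 and EIF4G2 were lower and ALDH1L2, CCND2 and LINC00963 higher in every DIS3-sh1 library than in every Scramble library.

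DIS3-sh1 changed a large part of the transcriptome in both directions. Of 19591 genes tested, 6751 were higher and 6379 lower in DIS3-sh1 (edgeR quasi-likelihood test), together 67.0% of the genes tested. Changes of at least 2-fold were more often increases, with 1984 called genes higher and 772 lower. The groups did not overlap for 69.8% of the genes tested, where chance gives 10%. The median log2 fold change of all tested genes was 0.02. TMM scaling sets the bulk of genes near 0, so this median and the balance of higher and lower calls depend on the scaling. With upper-quartile scaling, 7745 genes were higher and 5471 lower. A change in the total amount of RNA per cell cannot be seen in these values. With TMM scaling and without DIS3-sh1 replicate 1, which stands apart from the other 2 libraries of its group, 6567 genes were higher and 6269 lower.

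Among well expressed genes, EIF4G2, a translation initiation factor related to eIF4G, fell by 2.01 on the log2 scale, from 1252 ± 9.14 to 311 ± 6.52 CPM (SE 0.02, adjusted p = 5.97e-33). HSPA8, the constitutive cytosolic HSP70 chaperone, fell by 1.94, from 1749 ± 26.2 to 455 ± 14.5 CPM. CCND2, a D-type cyclin, rose by a log2 fold change of 1.96 ± 0.03, from 80.1 ± 1.47 to 312 ± 4.42 CPM. TSC22D3, the glucocorticoid-induced leucine zipper gene, rose by a log2 fold change of 1.81. EIF4G2, CCND2 and TSC22D3 were chosen after their values were seen.

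The 5 largest increases that met the naming rule were in PADI3, a peptidylarginine deiminase (log2 fold change 5.92 ± 0.54), LINC02154 (4.92 ± 0.48), FUT1, a fucosyltransferase of the H blood group antigen (4.84 ± 0.30), LGR6, an R-spondin receptor (4.38 ± 0.45), and LINC00886 (4.33 ± 0.46). They were almost silent in Scramble, so that these fitted values rest on few counts. PADI3 had 2 counts over the 3 Scramble libraries and 139 over the 3 DIS3-sh1 libraries, a depth-scaled ratio of 73.8 with an exact interval of 20.1 to 615 that covers counting error only. Without Scramble replicate 1, the log2 fold change was 6.29 for LGR6, 3.72 for LINC00886 and 4.32 for LINC02154, and without Scramble replicate 3 it was 5.28 for LINC00886. FUT1 reached the highest level of the 5, 4.60 ± 0.40 CPM in DIS3-sh1 against 0.15 ± 0.05 CPM in Scramble. The largest decreases were in HSPA1B (log2 fold change -3.92 ± 0.10) and HSPA1A (-3.80 ± 0.19), the stress-inducible HSP70 genes, followed by MYLK2, a myosin light chain kinase (-3.05 ± 0.31), DIS3 itself, and DOK3, a docking adaptor of tyrosine kinase signalling (-2.61 ± 0.18). HSPA1B fell from 45.9 ± 4.55 to 3.02 ± 0.46 CPM. HSPA1A and HSPA1B are near-identical copies on chromosome 6, 31815464 to 31817946 and 31827735 to 31830255, and reads may be split between them.

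The make-up of the libraries differed between the groups. Transcripts of long non-coding types took 3.55% to 3.56% of counts in Scramble and 4.86% to 4.99% in DIS3-sh1, while nuclear coding genes took 85.6% to 85.8% and 79.0% to 79.7%. Small structural RNAs took 5.07% to 5.28% of counts in Scramble and 8.43% to 9.61% in DIS3-sh1. RN7SL1, the RNA of the signal recognition particle and the highest gene in every library, took 1.63% to 1.71% and 2.79% to 3.21%, a log2 fold change of 0.78 ± 0.07 (adjusted p = 0.000601). Its reads may be split with its copies. DIS3-sh1 replicate 1 had the highest share of small structural RNA (9.61%) and the lowest share of mitochondrial counts in its group (2.78% against 3.42% and 3.47%).

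**Figure D2:**
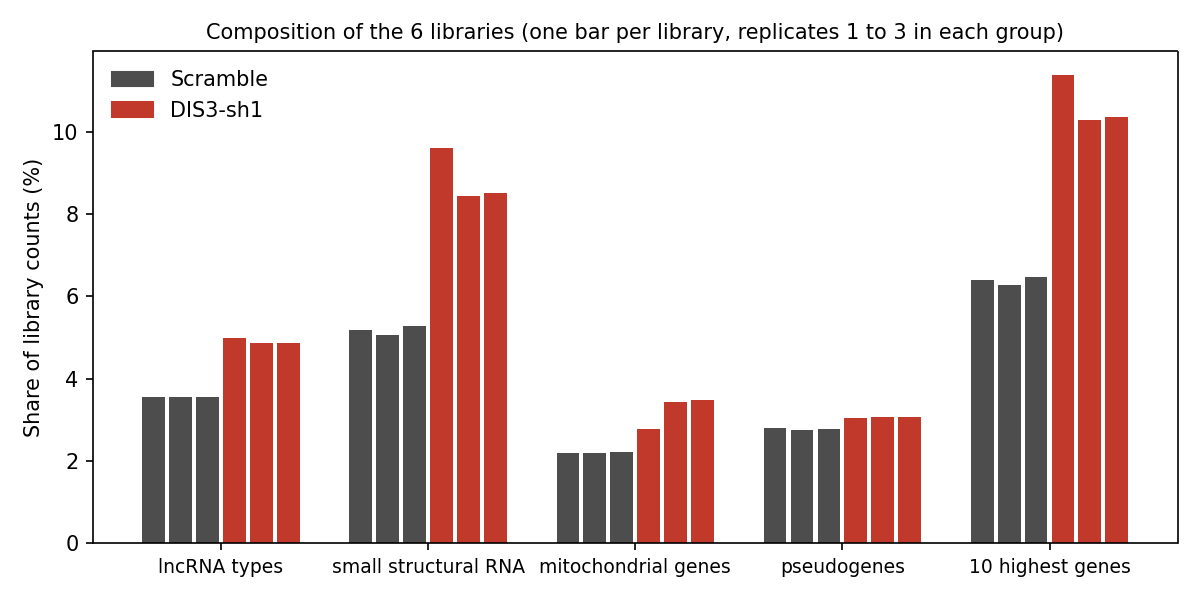
Share of all counts (%) taken by 4 classes of genes and by the 10 highest genes, with 1 bar per library and replicates 1 to 3 from left to right in each group. Small structural RNA made up 5.07% to 5.28% of the Scramble libraries and 8.43% to 9.61% of the DIS3-sh1 libraries.

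Non-coding transcripts that start at promoters or run antisense to genes rose. Of 330 tested divergent promoter transcripts (names ending in -DT), 198 rose, 13 fell and 119 were not called, with a median log2 fold change of 0.68 (camera, adjusted p = 2.0e-08). Adjusted over the list alone, 197 rose and 13 fell. GMDS-DT went from 8.75 to 22.4 CPM, and COPB2-DT from 4.34 ± 0.98 to 13.6 ± 0.57 CPM. Of 554 antisense RNAs (names ending in -AS and a number), 298 rose and 46 fell, with a median of 0.52 (adjusted p = 2.04e-06; 294 and 44 adjusted over the list alone). GABPB1-AS1 doubled, with a log2 fold change of 1.08 ± 0.05, whereas VPS9D1-AS1 fell by 1.04. Of 278 long intergenic RNAs named LINC, 134 rose and 26 fell, with a median of 0.47 (adjusted p = 0.000348; 132 and 25 adjusted over the list alone). LINC00963 rose by a log2 fold change of 1.78 ± 0.07 and LINC01033 by 2.75 ± 0.14, and LINC00641 fell by 1.24. All 3 lists also passed with an estimated correlation, at adjusted p = 0.00806, 0.0191 and 0.0468. Together they had a median of 0.56, and coding genes matched on mean CPM had a median of 0.32, a difference of 0.23. By annotated type, 520 of 1118 antisense genes rose and 111 fell, while 25 of 322 sense intronic transcripts rose and 73 fell (medians 0.49 and -0.28). The use of strand in counting is not stated, so reads of an antisense RNA and of the gene opposite cannot be told apart with certainty.

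Host genes of microRNAs went both ways. Of 30 tested, 12 rose and 6 fell (11 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.445), while fry, which tests a list on its own, called it higher (adjusted p = 0.00897). MIR34AHG, the precursor of the p53-induced miR-34a, rose by a log2 fold change of 2.01 ± 0.20 from 1.09 ± 0.12 CPM, and MIR17HG, the host of the miR-17-92 cluster, fell by 0.64. Host genes of snoRNAs also went both ways, with 7 higher and 11 lower of 26 (adjusted p = 0.491). SNHG17 fell by 1.36 and SNHG6 rose by a log2 fold change of 1.03. The median of the snoRNA host genes was -0.04 with TMM scaling and 0.04 with upper-quartile scaling.

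mRNAs of the RNA exosome and its cofactors fell as a group. Of 30 tested, 22 fell, 5 rose and 3 were not called, with a median log2 fold change of -0.29 (camera, adjusted p = 0.000948, and 0.0468 with an estimated correlation). Camera set this list, like the others, against all tested genes. Coding genes matched on mean CPM were not drawn for any list that fell. All tested coding genes had a median of -0.01, and 38.7% of them were called lower. DIS3 is not a member of the exosome list. The largest fall within the list was in SRRT, the ARS2 protein that links the cap-binding complex to RNA decay, from 221 ± 6.98 to 87.4 ± 1.56 CPM (log2 fold change -1.34 ± 0.03). Both cap-binding subunits fell, NCBP1 (-0.76) and NCBP2 (-0.78). Among core subunits, EXOSC4 (-0.93) and EXOSC3 (-0.79) fell, EXOSC1 and EXOSC8 rose by log2 fold changes of 0.34 and 0.21, and EXOSC5 and EXOSC7 were not called. EXOSC10, the other nuclear exonuclease of the complex, fell by 0.20 ± 0.04 on the log2 scale. C1D, an EXOSC10 cofactor, rose by a log2 fold change of 1.02 ± 0.11. The helicase gene MTREX fell by 0.10, and its call was lost with upper-quartile scaling (adjusted p = 0.601) and without Scramble replicate 2 (0.0582). The call of ZCCHC8 (0.13, adjusted p = 0.0245) was lost with DESeq2 (0.0875), without Scramble replicate 1 (0.184) and without DIS3-sh1 replicates 2 (0.0931) or 3 (0.118). EXOSC7 was called with upper-quartile scaling (adjusted p = 0.0101).

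Other RNA decay factors fell as well, 28 of 36 tested, with 5 higher and 3 not called (median -0.31, camera adjusted p = 6.09e-05, and 0.0388 with an estimated correlation). Among them were SMG5, a factor of nonsense-mediated decay (-0.87), CNOT7, a CCR4-NOT deadenylase (-0.79), and ISG20L2, a nucleolar exonuclease (-0.97). The 5 that rose were PAN2, a deadenylase subunit (1.15 ± 0.06), the decapping factor DCP1A (0.79), RNASEH2A (0.42), the 5' to 3' exonuclease XRN1 (0.27) and CNOT6L (0.18), of which the last 4 were chosen after their values were seen.

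Factors that act in the making or turnover of circular RNAs fell. Of 33 tested, 29 fell, 1 rose and 3 were not called, with a median of -0.37 (camera, adjusted p = 2.00e-08). The list missed the threshold with an estimated correlation (adjusted p = 0.0565). They include the SR splicing factor gene SRSF1 (-1.19), HNRNPM (-1.06), the stress granule protein gene G3BP1 (-0.96) and DHX9 (-0.90), a helicase gene whose product unwinds paired Alu repeats. EIF2AK2, the double-stranded RNA sensor PKR, was the member that rose (0.26 ± 0.04, named after its values were seen). Linear host genes of well studied circular RNAs went both ways, with 16 lower and 8 higher of 29 (median -0.10, and -0.02 with upper-quartile scaling, adjusted p = 0.132). POLR2A, the largest subunit of RNA polymerase II (-0.77), RTN4 (-0.96), CCNB1 (-0.78) and SMARCA5 (-0.61) fell. These are sums over all transcripts of a gene and say nothing about its circular products.

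Heat shock genes and genes of the proteasome and of ribosome assembly fell most uniformly. Of 17 heat shock genes, 16 fell and 1 rose, with a median of -1.16 (camera, adjusted p = 2.00e-08, and 0.0445 with an estimated correlation). HSPH1 (-2.05 ± 0.03), DNAJA1 (-1.71) and HSP90AA1 (-1.08) fell, as did the HSP70 transcripts above. The exception was HSPB1, a small heat shock protein gene (0.86 ± 0.09, named after its values were seen). Of 31 proteasome subunits, 30 fell and 0 rose, with a median of -0.65 (adjusted p = 3.31e-11, and 0.0136 with an estimated correlation). PSMD1 (-1.11), PSMA4 (-1.01), PSMD11 (-0.88) and PSMB2 (-0.84) fell, while PSMD4 was not called (-0.05 ± 0.04). Of 34 genes of ribosome biogenesis and the nucleolus, 33 fell and 0 rose, with a median of -0.72 (adjusted p = 5.55e-12, and 0.0136 with an estimated correlation), and 34 fell adjusted over the list alone. DKC1, the pseudouridine synthase of H/ACA particles (-1.24), NOP58, a box C/D core protein gene (-1.09), NOL11 (-0.90) and HEATR1 (-0.72) fell. BOP1 (-0.18 ± 0.07, adjusted p = 0.0551) was not called over all genes and was called with RLE scaling (adjusted p = 0.0322), limma-voom (0.0428), no filter (4.01e-05), the replicate number as a block (0.00321), without small structural, ribosomal and mitochondrial genes (0.0202) and without DIS3-sh1 replicate 1 (4.75e-07).

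Targets of ATF4, the transcription factor of the integrated stress response, rose. Of 30 tested, 25 rose, 3 fell and 2 were not called, with a median of 0.67 (camera, adjusted p = 1.69e-06, and 0.0295 with an estimated correlation). ALDH1L2, a mitochondrial folate enzyme, rose from 39.0 ± 0.51 to 193 ± 5.19 CPM (log2 fold change 2.31 ± 0.04, adjusted p = 3.22e-29). PCK2, mitochondrial phosphoenolpyruvate carboxykinase, rose by a log2 fold change of 2.63 ± 0.05, ASNS, asparagine synthetase, by 1.40 and SARS1, seryl-tRNA synthetase, by 0.86. The 3 that fell were the serine synthesis gene PSAT1 (-0.83), the amino acid transporter gene SLC7A5 (-0.83) and its partner SLC3A2 (-0.26), all named after their values were seen. Unfolded protein response genes, mostly chaperones of the endoplasmic reticulum, showed 12 lower and 2 higher of 20 (13 and 2 adjusted over the list alone). The list did not pass (median -0.14, and -0.06 with upper-quartile scaling, camera adjusted p = 0.0625). It passed without Scramble replicate 3 (adjusted p = 0.0484) and without DIS3-sh1 replicate 2 (0.0485). HSPA5, the BiP chaperone (-0.43), CALR (-0.44) and SEC61B (-0.66) fell, and HERPUD1 rose by a log2 fold change of 0.65.

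Other stress programmes went both ways. Of 24 p53 targets, 12 rose and 7 fell (median 0.21, camera adjusted p = 0.225): the cell cycle inhibitor gene CDKN1A rose by a log2 fold change of 0.90 and SESN2 by 0.80, and TIGAR (-1.41) and AEN (-0.82) fell. The cell line expresses large T antigen, which binds p53. Of 18 interferon-stimulated genes, 6 rose and 4 fell (median 0.21, adjusted p = 0.26). STAT2 doubled (1.01 ± 0.06), DDX60 rose by a log2 fold change of 1.78 from 2.69 ± 0.43 CPM, IFITM1 by 2.22 from 0.58 ± 0.20 CPM, and IFIT5 fell by 0.55. IFIT1 also fell, but lost its call with upper-quartile scaling (adjusted p = 0.0691), with DESeq2 (0.0663) and without Scramble replicate 2 (0.128) or DIS3-sh1 replicate 2 (0.131). The fall of HERC5 lost its call with upper-quartile scaling (0.229) and without DIS3-sh1 replicate 3 (0.0668). Of 27 immediate early genes, 10 rose and 8 fell (adjusted p = 0.362), among them KLF10 (1.35), JUN (0.75) and MCL1 (-0.51).

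Splicing regulators, histone genes and cell cycle genes were mostly lower. Of 21 SR proteins and their regulators, 17 fell and 2 rose (median -0.59, camera adjusted p = 1.71e-05), a call that was lost with an estimated correlation (adjusted p = 0.14). SRSF7 (-1.14), SRSF6 (-1.13) and SRSF2 (-1.09) fell. Of 58 replication-dependent histone genes, 47 fell and 7 rose (47 and 8 adjusted over the list alone), with a median of -0.47 (adjusted p = 3.57e-08, lost at adjusted p = 0.138 with an estimated correlation). H1-3 (-1.71), H2AC12 (-1.63), H2AC4 (-1.58) and H2BC18 (-1.47) fell, and reads may be split among these similar genes. Of 30 genes of G2 and mitosis, 25 fell and 4 rose (median -0.37, adjusted p = 1.82e-05, lost at adjusted p = 0.111 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex (-1.23), PLK1 (-0.82) and CCNB1 (-0.78) fell, whereas PRC1, a microtubule bundling protein gene, rose by a log2 fold change of 0.77. Of 28 genes of G1/S and DNA replication, 17 fell and 9 rose, and the list did not pass (adjusted p = 0.0625). UHRF1, which directs maintenance DNA methylation, fell by 1.76 ± 0.04, from 168 ± 3.78 to 49.5 ± 0.39 CPM. CDC6 (-0.79) and MCM6 (-0.62) fell less.

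Cholesterol synthesis genes fell. Of 23 cholesterol synthesis genes, 15 fell and 3 rose (median -0.41, camera adjusted p = 0.000943, and 0.0468 with an estimated correlation): HMGCS1 (-0.88) and FDFT1 (-0.59) fell, while SREBF2, which encodes a transcriptional activator of this pathway, rose by a log2 fold change of 0.84. Glycolysis and hypoxia genes showed 14 lower and 10 higher of 25, and the list did not pass camera (median -0.20, and -0.11 with upper-quartile scaling, adjusted p = 0.299; fry, which tests a list on its own, lower at adjusted p = 0.000799), with PGAM1 down by a log2 fold change of -0.97 and ENO1 and LDHA of -0.90 each. Of 34 nuclear genes of oxidative phosphorylation, 22 fell and 4 rose (median -0.20, and -0.12 with upper-quartile scaling, adjusted p = 0.00146, lost at adjusted p = 0.0716 with an estimated correlation), led by NDUFA8 (-0.98) and UQCRFS1 (-0.90). Of 13 mitochondrially encoded mRNAs, 6 rose and 2 fell (median 0.32, adjusted p = 0.116). MT-CO1 rose by a log2 fold change of 0.69 ± 0.03, MT-CO2 by 0.75 and MT-CO3 by 0.72. MT-ND1 (-0.48) and MT-ND6 (-0.57) were lower, and both lost their calls without Scramble replicate 1 (adjusted p = 0.0727 and 0.0575) and without Scramble replicate 3 (0.0719 and 0.0531), and MT-ND1 also without Scramble replicate 2 (0.0702). With the replicate number as a block, both were lost too (0.0687 and 0.0798). DIS3-sh1 replicate 1 had the lowest mitochondrial share of its group, and without it the list passed (adjusted p = 0.00196).

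Ribosomal protein mRNAs rose slightly. Of 81 tested, 48 rose and 15 fell (50 and 15 adjusted over the list alone), with a median of 0.12, and 0.20 with upper-quartile scaling (camera, adjusted p = 0.00492, lost at adjusted p = 0.111 with an estimated correlation). RPLP0 rose by a log2 fold change of 0.78, RPS2 by 0.61 and RPL3 by 0.47, and RPL19 fell by 0.53. Many of these genes have pseudogenes that can share their reads. Of 405 zinc finger genes named ZNF and a number, 179 fell and 95 rose, with a median of -0.16, and -0.08 with upper-quartile scaling (adjusted p = 0.0105, and 0.0468 with an estimated correlation). ZNF326 (-1.07) and ZNF207 (-0.76) fell, and ZNF362 rose by a log2 fold change of 1.24.

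Several abundant non-coding RNAs rose, and small nucleolar RNA genes fell more often than they rose. Of 15 abundant non-coding RNAs, 9 rose and 2 fell (median 0.20, camera adjusted p = 0.025, lost at adjusted p = 0.111 with an estimated correlation). The estimated correlation of this list was -0.034, under the preset 0.01, so correlated members did not cost it the call. NEAT1, the scaffold of paraspeckles, rose from 200 ± 3.85 to 474 ± 7.87 CPM (log2 fold change 1.24 ± 0.03), RN7SK, the RNA that holds P-TEFb inactive, by a log2 fold change of 0.68, and OIP5-AS1 by 0.68. KCNQ1OT1, a long nuclear RNA of an imprinted locus, fell by 0.98, and FTX (-0.79) fell too. Of 186 snoRNA and scaRNA genes, 72 fell and 15 rose (66 and 12 adjusted over the list alone), with a median of -0.56 (adjusted p = 6.45e-05, and 0.0388 with an estimated correlation). The summed level of these genes went the other way, from 4400 to 7482 CPM, and 3150 ± 281 CPM of the Scramble sum came from SNORD3A, the U3 RNA that has its own promoter. SNORD3A measured 8101 CPM in DIS3-sh1 replicate 1 and 4510 and 4608 CPM in the other 2, and was not called (log2 fold change 0.87 ± 0.29, adjusted p = 0.0555). It was called with upper-quartile scaling (log2 fold change 0.95, adjusted p = 0.0435), with DESeq2 (0.85, adjusted p = 0.00965) and without DIS3-sh1 replicate 1 (0.54, adjusted p = 0.0143). SCARNA10 and SCARNA12 rose by a log2 fold change of 0.65 each, and SNORD86 fell by 1.22. SNORD20 rose by a log2 fold change of 2.48 from 0.56 ± 0.17 CPM. Of 42 spliceosomal snRNA and 7SK genes and pseudogenes, 13 fell and 3 rose (13 and 2 adjusted over the list alone), and the list did not pass (median -0.33, adjusted p = 0.129). It passed without Scramble replicate 1 (adjusted p = 0.0469) and without DIS3-sh1 replicate 3 (0.0436).

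**Figure D3:**
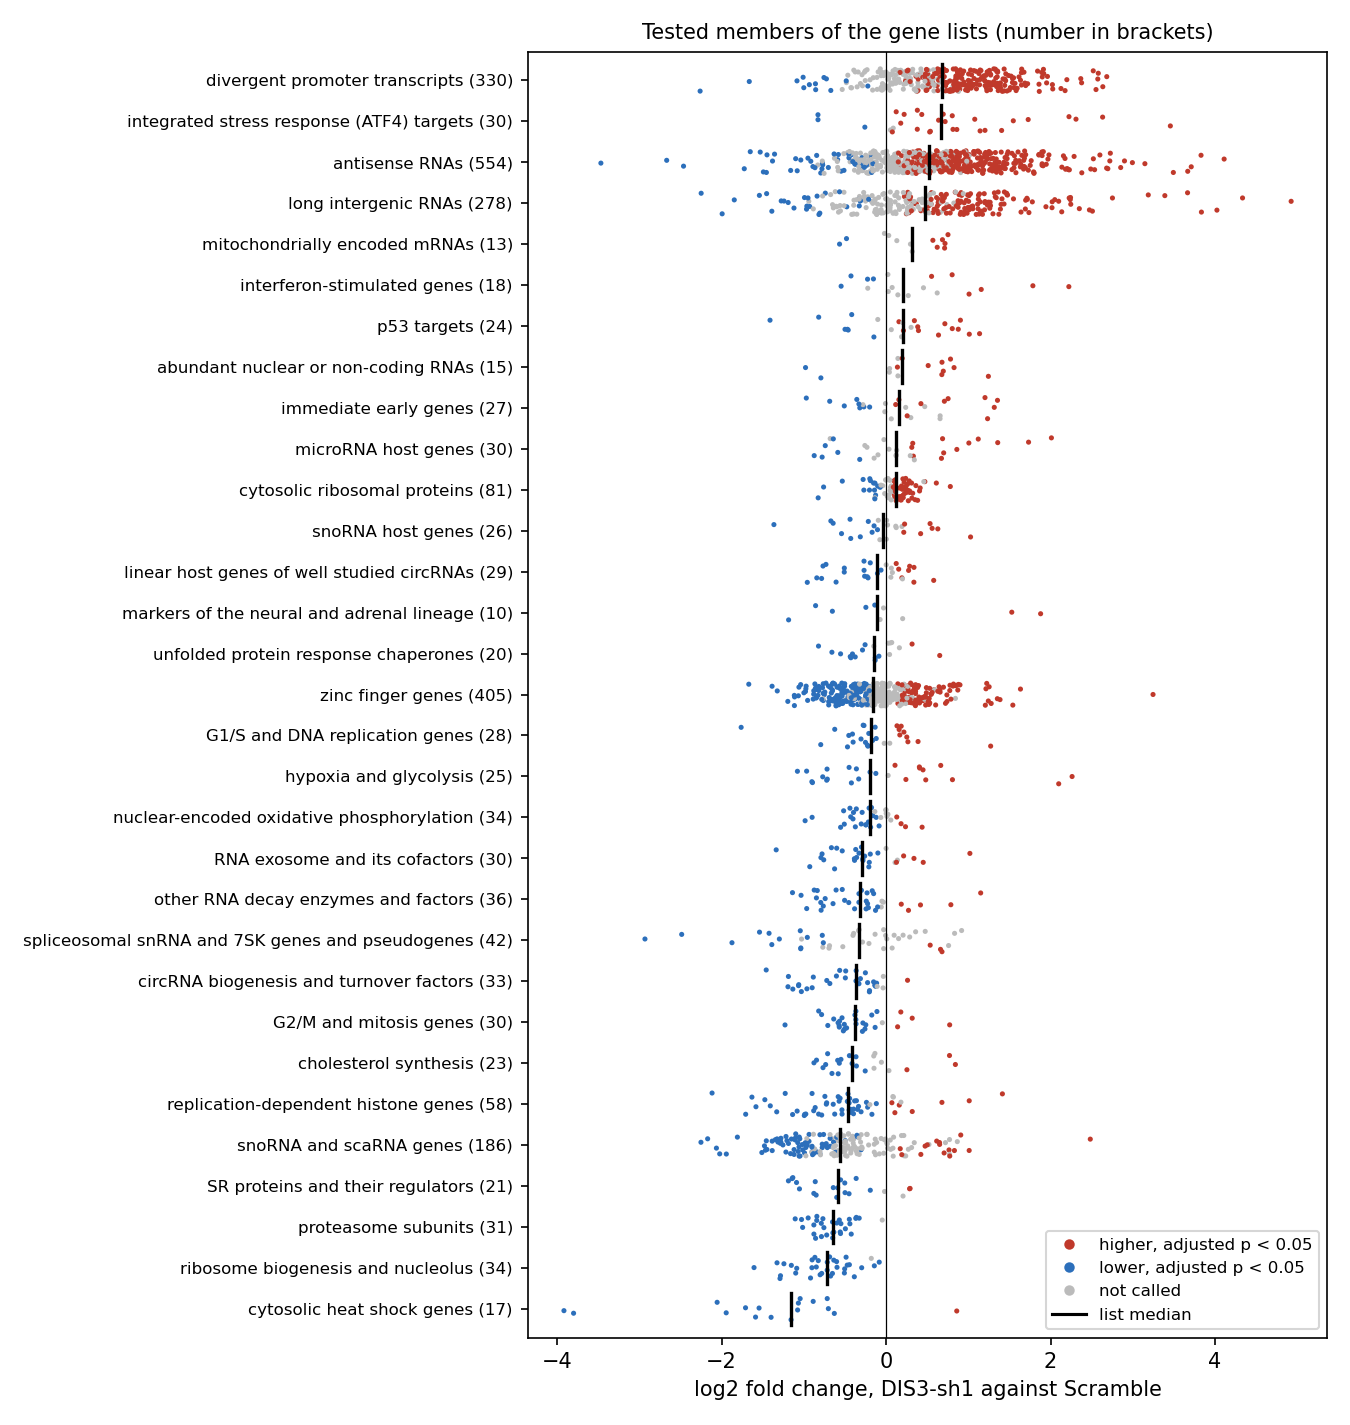
Log2 fold change of DIS3-sh1 against Scramble for each tested member (point) of the 31 gene lists with at least 5 tested members, ordered by the list median (black bar). Red and blue points passed the edgeR test as higher and lower and grey points did not. Divergent promoter transcripts have the highest median (0.68) and cytosolic heat shock genes the lowest (-1.16).

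Markers of other cell types went both ways. Among blood cell markers, HBA1 (0.97 ± 0.30 to 0.16 ± 0.02 CPM) and CD14 (0.71 ± 0.20 to 0.15 ± 0.09 CPM) fell and CD68 rose (0.45 ± 0.03 to 1.09 ± 0.17 CPM). Of 3 fibroblast and endothelium markers, COL1A1 rose by a log2 fold change of 0.76 from 14.7 ± 0.46 CPM, and COL3A1 and PDGFRA were not called. Of 4 epithelial markers, KRT8, a simple epithelial keratin gene, rose from 4.65 ± 0.22 to 32.6 ± 0.81 CPM (log2 fold change 2.81 ± 0.09), CDH1 from 3.76 ± 0.46 to 8.43 ± 1.27 CPM and KRT18 from 48.7 ± 1.96 to 59.1 ± 1.57 CPM, and EPCAM was not called. These lists had too few tested members for camera. Of 10 markers of the neural and adrenal lineage, 5 fell and 2 rose (camera, adjusted p = 0.398). The neuronal filament gene INA (-1.19) and SYP (-0.86) fell, and MAP2 rose by a log2 fold change of 1.88. The fall of NEFM lost its call with upper-quartile scaling (adjusted p = 0.266), and that of SNAP25 without DIS3-sh1 replicate 1 (0.139).

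For 24 of the 34 lists, the counts of higher and lower members adjusted over the list alone were the same as those given. With the preset correlation 19 of 31 lists passed, and 12 of these, in the same direction, with the estimated correlation. Further lists that did not pass camera were called by fry, which tests a list on its own. Fry called p53 targets (adjusted p = 0.000126), interferon-stimulated genes (0.000975), immediate early genes (0.00126) and mitochondrially encoded mRNAs (0.0488) higher. It called G1/S genes (4.84e-07), unfolded protein response genes (6.66e-05), linear hosts of circular RNAs (0.000112) and neural and adrenal markers (0.00711) lower. Only 1 shRNA against DIS3 is analysed here, so effects of the shRNA sequence on other transcripts are not separated from those of the loss of DIS3.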

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

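The tests chosen after the data were seen in this part are the replicate block combined with an estimated correlation and the re-reading of results without DIS3-sh1 replicate 1 as the library that stands apart. The number of genes called between DIS3-sh1 and Scramble (13130) lay between 11986 (DESeq2) and 13479 (no filter on low counts) under other scalings, tests, filters and library compositions. It lay between 12537 and 12836 when each library was left out in turn. Every gene called in both ran in the same direction under all of these. Upper-quartile scaling shifted the median log2 fold change by 0.08 and raised the share of higher calls from 51.4% to 58.6%. A test against a fold of 1.2 left 8787 genes, 4731 higher and 4056 lower, since it asks for a larger change. The log2 fold change of DIS3 lay between -2.73 and -2.63 in all alternatives. Of the 209 other named genes, 168 kept their direction and their side of the threshold in every alternative that held them (201 were held by the filter at 1 CPM and 189 by the set without small structural, ribosomal and mitochondrial genes), none reversed, and 18 changed side under an alternative other than the fold test. The 31 lists gave 19 calls, 12 with the estimated correlation and 29 with fry, which asks only whether a list moves. Leaving out a library gave 19 or 20. The replicate numbers showed no clear pairing of the libraries: deviations of same-numbered libraries from their group means correlated at 0.04, 0.01 and 0.01. Other pairs across the groups gave -0.02 to 0.01. These correlations run over all tested genes, many with few counts, so a weak pairing is not excluded. With the number as a block anyway, 13166 genes and 19 lists were called. The block together with an estimated correlation called 0 lists, where camera rests on 2 residual degrees of freedom. For this count of 0, camera with the block and the preset correlation gave 19 and fry without the block 29. The comparisons planned for DIS3-sh2 were not run, and the fit of only the 2 groups is the one reported. In the simulation, changes of 1.5-fold were called for 66% of genes. It changed 200 of 19591 genes, whereas 67.0% of genes were called in the data. The unadjusted p needed for a call was therefore stricter in the simulation, and its shares need not carry over. Small changes can still be missed. Genes near 1 CPM were not simulated apart, so how many of their changes are missed was not measured.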

Other observations

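Of the tests in this part, those of genomic DNA or unspliced RNA, of other splits of the libraries and of the flanking base of a sequence word were chosen after the result was seen. Other splits of the 6 libraries into 3 and 3 called 0 genes in each of the 9 cases, and the real split called 13130 (1 of 10 splits with as many). At an unadjusted p under 0.05, the other splits gave at most 106 genes in edgeR and the real one 13632. With 10 splits the share cannot fall under 0.05. Each of the other splits put libraries of both groups on each side. The group difference then widens the spread within the sides, which by itself lowers the number of calls. These splits therefore do not measure how many calls arise by chance.

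The rise of -DT, -AS and LINC transcripts (1162 genes, median log2 fold change 0.56, bootstrap interval 0.51 to 0.62) was set against 4 technical causes. Genomic DNA or unspliced RNA in the DIS3-sh1 libraries would raise sense intronic transcripts too, but their median was -0.28 (-0.35 to -0.22, 322 transcripts). For -DT transcripts, reads shared with the partner gene are argued against by a paired median difference of 0.82 (0.71 to 0.90, 329 pairs, partner median -0.11). The -AS and LINC transcripts were not paired with a gene. For them, shared reads were not tested and stay open, since the use of strand in counting is not stated. After a trend with GC content and length was removed, the median was 0.69. That trend was fitted on coding genes and explained 4.17% of the variance of their fold changes. The value therefore speaks only against a trend like that of coding genes, and one particular to non-coding transcripts was not tested. A shift of all weakly expressed genes could account for part: coding genes matched on mean CPM had a median of 0.32 (0.26 to 0.38 over 10000 random lists), which leaves 0.23 beyond it. Loss of DIS3, whose complex is known to degrade such transcripts, stays a hypothesis, since the effect of the shRNA on other targets is open with 1 shRNA.

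The fall of heat shock, proteasome and ribosome biogenesis genes (82 genes, median -0.76) stayed at a median of -0.67 (-0.78 to -0.60) after the trend with GC content and length was removed. Direct action of the shRNA on most of these genes through a seed match would need 1 word of 7 bases from the DIS3 mRNA in the 3' UTRs of most of the 79 members called lower. The highest share of any such word with a negative relation to fold change was 46.8% (37 of 79, exact interval 35.5% to 58.4%), and 50% of all 13694 genes searched carry that word. The interval spans the preset bound of 50%. The highest share among 6784 words falls on a common word, and the members carried it no more often than all genes searched. The test therefore could not decide whether a seed match acts on most or on part of these genes. A seed of the other shRNA strand, sites outside the 3' UTR and effects that follow from a changed regulator were not tested.

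A hypothesis on the shRNA itself came from the same search. Of 16162 words tested, ATAGATC had the strongest negative relation to fold change (z = -5.61, effect -0.14, 879 genes). It occurs in the DIS3 mRNA at chromosome 13, 72765991 to 72765997 and 72777446 to 72777452 (hg38, minus strand). The former position is coding or 3' UTR, depending on the annotated transcript, and the latter is coding. The DIS3 mRNA holds 6784 of the words tested, the next in rank are T-rich words of the DIS3 mRNA that many genes carry (TGTTTTT, z = -5.21, 6127 genes), and words absent from it reached a z of -4.28. If ATAGATC pairs with the seed of the DIS3-sh1 guide, sites followed by an A should go with the lowest values, as is known for microRNA sites. The median adjusted log2 fold change was -0.23 for 330 genes with ATAGATC followed by A, -0.11 for 549 genes with other ATAGATC sites, -0.10 (-0.14 to -0.04) for 804 genes with only its last 6 bases followed by A, and -0.07 for 12011 genes with neither ATAGATC nor its last 6 bases followed by A. The difference between both kinds of carriers was -0.12 (-0.20 to -0.02). The interval of the class with 6 bases covers the value of genes with neither, so this weaker kind of site shows no clear effect. A modest seed effect of the shRNA on genes with ATAGATC may be present but is not established, and 2 of the 79 genes above (2.53%, against 6.42% of all genes searched) carry the word. The sequence of the shRNA was not given in the sources used here.

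The fall of snoRNA genes sits in weakly detected members: 168 genes under a mean of 10 CPM had a median of -0.60 (70 lower, 6 higher), and 18 genes above it a median of 0.49 (2 lower, 9 higher). Loss of short RNAs by size is a candidate explanation, as fold change rose with gene length (Spearman's rho = 0.34 across 186 genes, which are not independent replicates, 0.20 to 0.48), although rho was 0.19 among the weak genes alone. Box C/D genes (median -0.63, 93 genes) and the longer box H/ACA genes (-0.57, 80 genes) hardly differed, and 13 scaRNA genes had a median of 0.01. A fall of the host genes is argued against by a paired median difference of -0.44 (-0.55 to -0.25, 173 pairs, host median -0.15). Reads from unspliced host introns in place of mature snoRNAs were not tested and stay open.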
